A study of Mus musculus with 12 samples.

How the data were processed

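RNA was measured in 12 samples of mouse tibialis anterior, 3 in each of 4 groups: WT and dKO, innervated and denervated, sampled 48 h after transection of the sciatic nerve at 7 weeks of age. The groups and replicate numbers were taken from the labels. Per the labels, total RNA was depleted of ribosomal RNA and made into strand-specific libraries. The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat2 2.0.14, Bowtie without a version, HTSeq 0.6.1 and the genome build mm9, with no role or order, and the annotation release, the filters and the strand setting of the counting are not given in the sources used here. The labels give 3 biological replicates per group and do not say which animal each leg came from, and the p-values here measure the spread between samples.

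The deposited table holds raw read counts per gene, per the file headers, and these counts were used for all tests. It also holds normalized counts, a signal made by the authors by dividing each library's counts by 1 factor. The method of that factor is not stated in the file headers, and its ratio to a median-of-ratios factor computed from the counts was 1.0 in all 12 libraries. A further set of columns holds the deposited normalized signal per kb of gene length, with the definition of length not given. The log2 fold changes in the table are the authors' own, with the first-named group over the second, so their sign was turned for comparison with the values here. The authors' p-values and adjusted p-values stand beside them as deposited, per the file headers, with the testing tool not stated. The last pair of p-value columns repeats the header of the innervated genotype comparison and follows the log2 fold change of the denervated one, and it was read as belonging to the latter.

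Of 31057 genes in the table, all with a gene ID, edgeR's filter by group kept 17201, which hold 99.975% of the counts. A symbol shared by more than 1 gene ID occurs 178 times, and genes were handled by ID. Library totals are given in the report. At these depths 3 counts correspond to 0.0342 to 0.0539 CPM per library, and this floor covers counting error only. Counts were scaled by TMM and fitted in 1 model of 4 group means with 8 residual degrees of freedom (R 4.3.3, edgeR 4.0.16, limma 3.58.1). Contrasts were tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The contrasts are dKO over WT in innervated legs, dKO over WT in denervated legs, denervated over innervated in WT and in dKO, and the difference between the latter 2 (interaction). Standard errors and 95% intervals were derived from the F statistic of the same fit.

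The comparisons, alternatives, 36 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 695 entries found in the table and 5 that are not. Each list was tested with camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of changed members are given at the threshold over all genes and, where they differ, adjusted over the list alone. Named genes are H2afz and H2afv, the 10 with the largest rise and the 10 with the largest decrease among called genes with a mean of at least 1 CPM and non-overlapping groups, and up to 4 called genes per list with the largest change. For the denervation contrasts and the interaction a set chosen in advance was added: Chrna1, Chrnd, Chrng, Musk, Myog, Myod1, Runx1, Ncam1, Gadd45a, Fbxo32, Trim63, Hdac4, Dach2, Ppargc1a, Myh4, Pvalb and Arntl. Some genes that this rule names are not reported here. Predicted genes, small RNAs, sex-linked genes and genes with a near-identical copy were left out of the sets of 10. Copies were searched among GENCODE M21 transcripts (GRCm38, another build than that of the notes) with BLAST 2.17.0 at 98% identity over 50% of the length, for 817 genes, of which 811 had a transcript there and 42 a near-identical copy. Exon overlaps, gene order, positions and GC content came from the same annotation, with GC content found for 91.4% of genes and for 97.7% of those with a mean of at least 1 CPM.

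Whether equal replicate numbers mark 2 legs of 1 animal was checked on the deviations of 12701 genes from their group means. The correlation between legs of the same number was 0.28 to 0.483 in WT and 0.206 to 0.535 in dKO, against −0.4 to 0.087 and −0.412 to 0.092 for different numbers, and each of the 6 libraries of a genotype had its highest value with the other leg of its own number. Denervation and interaction contrasts were therefore also run with the genotype and replicate number as a block, called a term for replicate number in the report. The genotype contrasts, which lie between animals, were run with the replicate number as an additive block as an alternative only. The paired fits called 8498 genes after denervation in WT and 8186 in dKO.

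The alternatives were RLE size factors, scaling by library totals only, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter at 1 CPM in at least 3 libraries, abundant and mitochondrial genes left out, sex-linked genes left out, only the groups compared in the fit, the replicate block, a 2-fold limit, and each library left out in turn. Alternatives chosen after seeing the data were an offset that removes each library's trend with GC content, that offset together with the replicate block, and leaving out the 2 libraries with the lowest correlation with GC content. The procedure was tested on simulated data with 200 changed genes per contrast. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.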

Results

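The 12 libraries come from the tibialis anterior muscle of 7-week-old C57BL/6 mice in 4 groups of 3. Control mice (WT) carry floxed copies of both genes for the histone variant H2A.Z, H2afz (H2A-Z.1) and H2afv (H2A-Z.2), and no Cre. Double-knockout mice (dKO) carry the same alleles and HSA-Cre, a Cre recombinase driven by the human skeletal actin promoter, which is active in muscle fibres. The sciatic nerve of the left leg was transected 48 h before sampling (denervated), and the unoperated leg of the other side served as the innervated sample. The questions are which genes differ between genotypes in resting muscle, which differ in denervated muscle, how each genotype responds to the loss of its nerve, and whether the 2 responses differ. Counts per library, for replicates 1, 2 and 3, summed to 81655612, 55668606 and 71822213 in WT innervated, 69016055, 87753152 and 73578048 in WT denervated, 71144019, 72527180 and 61566971 in dKO innervated, and 70774010, 68488996 and 69691897 in dKO denervated legs. The table lists 31057 genes, of which 17201 had enough counts to be tested. All 12 libraries had more CPM (counts scaled for library size) of the Y-linked gene Ddx3y than of Xist, the RNA of the inactive X chromosome. The giant sarcomere gene Ttn took 16.3 ± 0.371% of all counts in WT innervated and 12.6 ± 0.821% in WT denervated legs (mean ± SD, n = 3), and 16.1 ± 0.589% and 12.6 ± 0.266% in dKO. Changes below are log2 ratios with standard errors from edgeR, with TMM scaling, and n = 3 libraries per group throughout. Changed, rose and fell mean an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

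H2afv (ENSMUSG00000041126, chromosome 11, 6427229 to 6444443, minus strand) fell to 25.6% of its control level in innervated and 24.1% in denervated legs. Its raw counts were 1797, 1304 and 1175 in WT innervated, 1636, 2052 and 1530 in WT denervated, 337, 396 and 352 in dKO innervated, and 392, 341 and 368 in dKO denervated legs. These are 22.1 ± 3.17, 20.7 ± 1.56, 5.67 ± 0.53 and 5.0 ± 0.35 CPM. The dKO to WT change of H2afv was −1.96 (SE 0.12, edgeR adjusted p = 8.89e-06) in innervated and −2.05 (SE 0.12, edgeR adjusted p = 5.23e-06) in denervated legs. H2afz (ENSMUSG00000037894, chromosome 3, 137864487 to 137866922, plus strand) kept more of its counts. They were 1039, 596 and 993 in WT innervated, 844, 718 and 845 in WT denervated, 566, 453 and 577 in dKO innervated, and 569, 413 and 463 in dKO denervated legs, or 13.5 ± 2.38, 9.72 ± 1.92, 8.39 ± 1.60 and 6.56 ± 1.11 CPM. Its dKO to WT value was −0.69 (SE 0.19, 95% interval −1.09 to −0.28, edgeR adjusted p = 0.175, 62.2% of WT) in innervated and −0.57 (SE 0.19, −0.97 to −0.16, edgeR adjusted p = 0.287, 67.6% of WT) in denervated legs, so it did not pass in either. The call of H2afz depends on the method: over the alternatives its adjusted p ran from 0.00528 to 0.493 in innervated and from 0.0434 to 0.733 in denervated legs. A near-identical copy of H2afz lies within transcripts of Tmcc1, so its count is uncertain in that respect, and H2afv has 0 such copies. After denervation H2afz was at −0.47 in WT (edgeR adjusted p = 0.0539) and −0.36 in dKO (0.154). With a term for the replicate number its adjusted p by edgeR was 0.00656 in WT and 0.035 in dKO, where the alternatives ran from 0.0061 to 0.317 and from 0.035 to 0.454. Leaving out WT_innervated 2 (adjusted p = 0.0283 by edgeR) or WT_denervated 1 (0.0381) also brought the WT value past the threshold. H2afv was at −0.10 (adjusted p = 0.534 by edgeR) and −0.18 (0.25) after denervation.

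**Figure D1:**
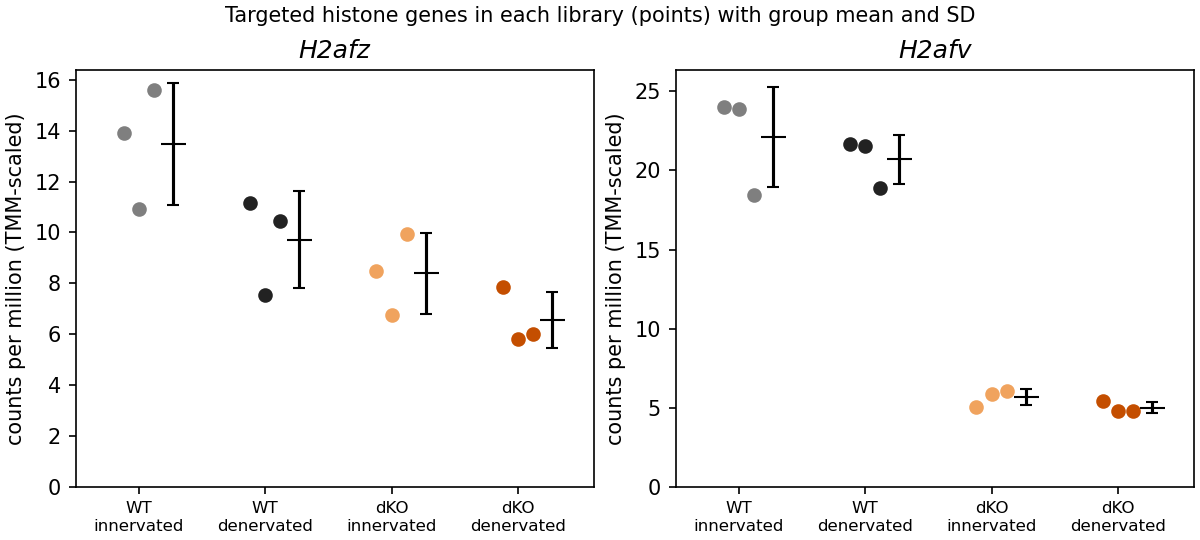
CPM of H2afz and H2afv per library in the 4 groups, with group mean and SD (n = 3). H2afv went from 22.1 ± 3.17 CPM in WT to 5.67 ± 0.53 CPM in dKO innervated legs, H2afz from 13.5 ± 2.38 to 8.39 ± 1.60 CPM.

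Between genotypes in innervated muscle, 79 genes changed, 25 higher and 54 lower in dKO, and 10 and 19 of them by 2-fold or more. An unadjusted p below 0.05 was reached by 1814 genes where 860 are expected by chance. Among the genes the naming rule takes, the largest rise was in Casr, the calcium-sensing receptor, from 5.65 ± 0.847 to 22.8 ± 4.07 CPM (2.01, SE 0.25, edgeR adjusted p = 0.00436). Other rises were in Gins1, a part of the replicative helicase (1.40, SE 0.22), the mitotic kinesin Kif20a (1.19, SE 0.22), the junction resolvase Gen1 (0.84, SE 0.15) and the RNase H2 subunit Rnaseh2b (0.69, SE 0.105). The mitochondrial folate enzyme Mthfd2 rose from 3.37 to 7.14 CPM (1.08, SE 0.16, edgeR adjusted p = 0.00904). Fam55c (1.07), Mfsd4 (0.96), the tRNA guanylyltransferase gene Thg1l (0.73) and the Rac exchange factor gene Tiam1 (0.72, from 11.6 to 19.1 CPM) also rose. Snph, which anchors mitochondria in axons, decreased from 1.93 to 0.443 CPM (−2.11, SE 0.26, edgeR adjusted p = 0.00436). Cntnap2, of the neurexin family, decreased from 5.17 to 1.31 CPM (−1.98, SE 0.21, adjusted p = 0.00144 by edgeR) and so did the synaptotagmin Syt3 (−1.70, SE 0.22). Dach2, a corepressor that restrains synaptic genes in innervated muscle, decreased from 4.91 to 1.5 CPM (−1.71, SE 0.21, adjusted p = 0.00436 by edgeR). Zfp286 (−1.28), the Groucho-family gene Tle6 (−1.21), the carbonic anhydrase relative Car11 (−1.15) and Lrp2bp (−1.13) were lower as well. H2afv aside, Plekhb1 had the smallest adjusted p of this group by edgeR (adjusted p = 0.000696, −1.17, SE 0.11, from 17.7 to 7.86 CPM). Exons of Kif20a, Mfsd4, Rnaseh2b, Zfp286 and Lrp2bp overlap a gene on the other strand and are uncertain in that respect. In all 79 genes the 3 dKO values lay outside the range of the 3 WT values, against 17.1% of all tested genes and 10% expected by chance. The call was made on the same values and favours such separation, so this adds no support. Casr, Mfsd4, Thg1l, Snph, Cntnap2, Dach2, Syt3, Tle6 and Plekhb1 stayed called with each of the 6 libraries left out in turn, while the total was 44, 40 and 34 without WT_innervated 1, 2 and 3 and 41, 27 and 52 without dKO_innervated 1, 2 and 3. The number called was 264 with DESeq2, which also replaces the filter on low counts by its own, 240 with edgeR without a filter, 46 with only these 2 groups in the fit and 50 without the libraries dKO_innervated 1 and WT_denervated 2, described below.

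As groups, 8 lists lay higher and 1 lower in dKO innervated muscle by camera at its preset correlation, each by a small amount and with few single genes behind it. With an estimated correlation the adjusted p = 0.903 for each of the 9. Ribosomal proteins had a median of 0.19 (camera adjusted p = 7.34e-11) with 0 of 40 genes changed, or 15 risen when adjusted over the list alone. Oxidative phosphorylation stood at 0.13 (camera adjusted p = 2.65e-07, 0 of 48), the citrate cycle and fat oxidation at 0.13 (0.00035, 0 of 34) and the proteasome at 0.11 (0.000739, 0 of 31). Mitochondrially encoded genes stood at 0.16 (camera adjusted p = 0.0385, 0 of 12). Macrophage genes (median 0.29, camera adjusted p = 0.00347, 0 of 20) and interferon-induced genes (0.22, 0.0183, 0 of 24) lay higher. Proliferation genes were at 0.20 (camera adjusted p = 0.0183) with Kif20a the 1 of 28 that rose, or 2 adjusted over the list alone. Endothelial genes lay lower (−0.12, camera adjusted p = 0.0102, 0 of 15). The list of synaptic and denervation-responsive genes had 1 of 26 changed, Dach2, and its camera adjusted p = 0.464 (0.903 with an estimated correlation). The genes that deposit or remove H2A.Z had 0 of 23 changed, 1 risen adjusted over the list alone (camera adjusted p = 0.886, with an estimated correlation 1). Library dKO_innervated 1 carried less of its signal in GC-rich genes than the others (correlation of its deviation with GC −0.263), as did WT_denervated 2 (−0.364), against −0.157 to 0.196 in the other 10. With the GC trend removed and a term for replicate number, 6 of the 9 lists stayed called. Proliferation (median 0.164, adjusted p = 0.0721 by camera), endothelial (−0.089, 0.0525) and mitochondrially encoded genes (0.092, 0.134) did not.

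In denervated muscle 62 genes changed between genotypes, 13 higher and 49 lower in dKO, 2 and 18 by 2-fold or more. An unadjusted p below 0.05 was reached by 1683. Among the genes the naming rule takes, the largest rise was in Fhl1, a LIM protein of muscle, from 422 to 801 CPM (0.92, SE 0.17, edgeR adjusted p = 0.0382). Mthfd2 rose from 8.23 to 15.1 CPM (0.87, SE 0.15, edgeR adjusted p = 0.032). Rnaseh2b (0.64), Ralgps1 (0.58), Isoc1 (0.52), the mismatch-repair gene Msh3 (0.52), Ccdc90b (0.46) and Tiam2 (0.41) followed. Kremen1, a receptor for the Wnt inhibitor Dkk, rose from 162 to 214 CPM (0.40, SE 0.07, edgeR adjusted p = 0.0293). Among those genes, H2afv aside, the largest decrease was in Hnmt, which inactivates histamine (−1.59, SE 0.20, edgeR adjusted p = 0.00433). Dach2 was again lower, at 0.65 against 1.79 CPM (−1.46, SE 0.23, edgeR adjusted p = 0.0181). Ctnna3, the alpha-T-catenin of striated-muscle junctions, decreased from 9.88 to 4.19 CPM (−1.24, SE 0.12, edgeR adjusted p = 0.00121). Car11 (−1.26), Tle6 (−1.23), Mtap9 (−1.17), Plekhb1 (−1.01, from 28.7 to 14.3 CPM) and the F-box gene Fbxo44 (−0.90) were lower. Mstn, the secreted inhibitor of muscle growth, decreased from 55.7 to 29.4 CPM (−0.92, SE 0.17, edgeR adjusted p = 0.0455). Exons of Rnaseh2b, Msh3, Ccdc90b and Tiam2 overlap a gene on the other strand. Of the genes called in innervated and in denervated legs, 32 were lower and 3 higher in both, and 0 had opposite signs. Legs of equal number vary together, so this overlap is not that of independent samples: the genotype effects of the 2 legs correlated at 0.567 over genes, against 0.064 to 0.564 for other splits of the replicate sets. All 62 genes had non-overlapping groups, against 14% of tested genes and 10% by chance, which again largely follows from the call itself. Hnmt, Ctnna3, Tle6 and Plekhb1 stayed called with each library left out, while the total was 38, 42 and 13 without WT_denervated 1, 2 and 3 and 22, 11 and 32 without dKO_denervated 1, 2 and 3. The number called was 289 with DESeq2 and its own filter, 252 with edgeR without a filter, 4 with only these 2 groups in the fit and 102 with the GC trend of each library removed. Of the 18 named genes besides H2afv and H2afz, 2 stayed called under every alternative, a 2-fold limit included. The main fit takes the legs as independent, so its 8 residual degrees of freedom may overstate what is known of the spread between animals.

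In dKO denervated muscle 6 lists lay higher by camera at its preset correlation, and with an estimated correlation the adjusted p = 0.869 for each. Ribosomal proteins had a median of 0.20 (camera adjusted p = 8.6e-14; 0 of 40 changed, 2 risen adjusted over the list alone). Oxidative phosphorylation was at 0.16 (camera adjusted p = 4.09e-11, 0 of 48), the proteasome at 0.17 (1.03e-08, 0 of 31), the citrate cycle and fat oxidation at 0.13 (2.78e-05, 0 of 34) and mitochondrially encoded genes at 0.18 (0.00564, 0 of 12). Core sarcomere genes were at 0.10 (camera adjusted p = 0.00148; 0 of 23, 3 risen adjusted over the list alone). Macrophage genes were at 0.07 (camera adjusted p = 0.0508, 0 of 20 changed), matrix-producing fibroblast genes at 0.13 (0.0925, 0 of 20) and autophagy genes at 0.06 (0.0925, 0 of 23, 1 risen adjusted over the list alone), each at 0.869 with an estimated correlation. With the GC trend removed and a term for replicate number these 3 passed as well (camera adjusted p = 0.0326, 0.0399 and 0.0326), and all 6 lists stayed called. Dach2 was the 1 of 26 synaptic and denervation-responsive genes to change (camera adjusted p = 0.514, with an estimated correlation 0.893). Mstn was the only changed gene on the list of ubiquitin ligases and growth regulators (camera adjusted p = 0.458, with an estimated correlation 0.869), and Mthfd2 the only one on the unfolded-protein and integrated-stress list (0.131 and 0.869). Of the genes that deposit or remove H2A.Z, 0 of 23 changed (camera adjusted p = 0.442, with an estimated correlation 0.869).

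**Figure D2:**
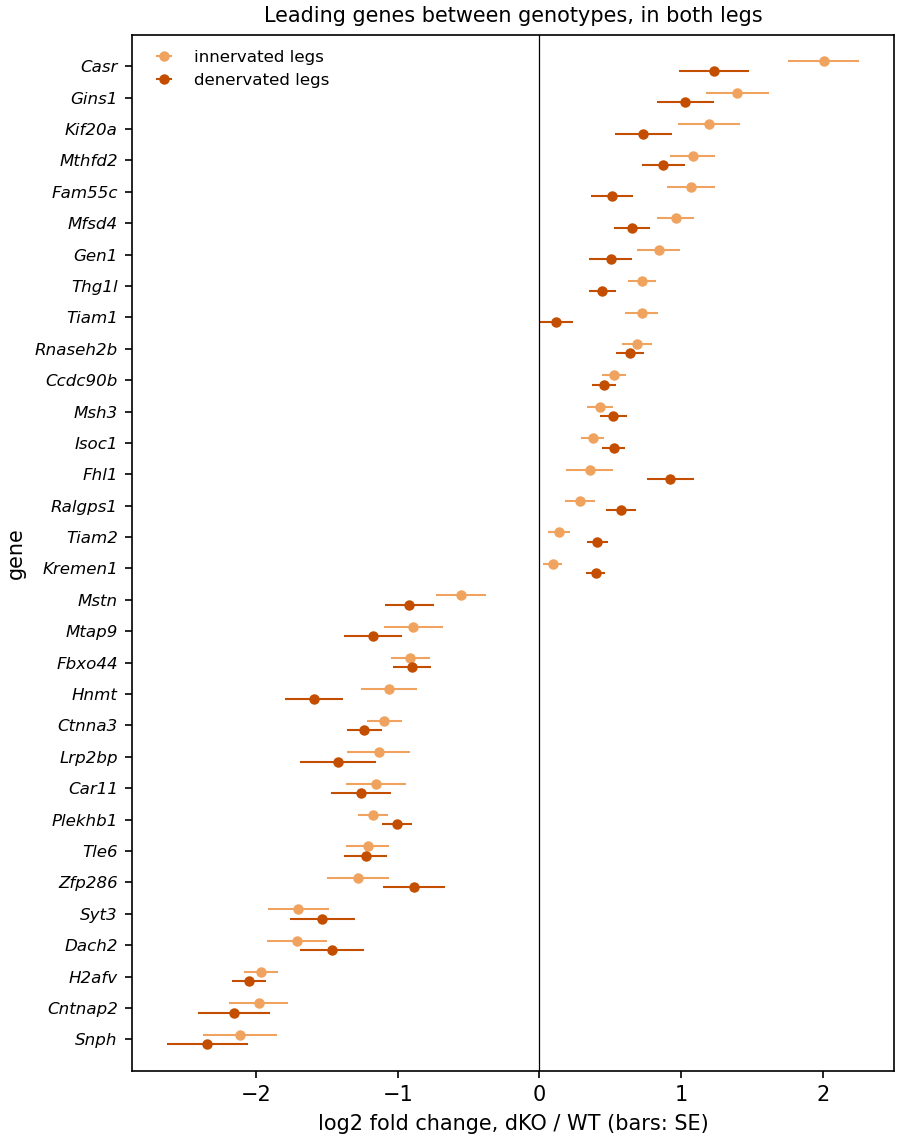
Log2 change of dKO over WT (± SE, n = 3 per group) of the leading genes in innervated and denervated legs. Casr stands at 2.01 and Snph at −2.11 in innervated legs, and Dach2 is low in both (−1.71 and −1.46).

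Denervation for 48 h changed 7576 genes in WT (3968 up, 3608 down; 44% of those tested) and 7233 in dKO (3761 up, 3472 down; 42%). The innervated leg was unoperated and on the other side, so surgery and side cannot be told apart from loss of the nerve here. Of the changed genes, 981 up and 1049 down in WT and 966 and 999 in dKO changed by 2-fold or more. Among the largest rises was that of the BMP-family ligand Gdf5 in WT (0.282 ± 0.0396 to 51.4 ± 13.4 CPM, 7.49, SE 0.29, edgeR adjusted p = 1.62e-09), which was at 7.63 in dKO (SE 0.29, edgeR adjusted p = 1.34e-09). Others were the acetylcholine receptor subunit Chrna9 (7.45, 6.45), the keratins Krt18 (7.27, 8.30) and Krt8 (6.79, 7.17), the neutrophil protein S100a8 (6.95, 7.64), the AP-1 subunit Fosl1 (6.79, 7.32) and the small GTPase Rrad (6.48, 6.58). In WT the next were Syt4 (6.17) and the chemokine Cxcl10 (6.17), and in dKO Prrt3 (6.53) and Ces2c (6.34). Among named genes the largest decrease in WT was in Fgf6, a growth factor of muscle (−5.11, SE 0.435). The potassium channel Kcnc1 went from 186 ± 14.2 to 5.88 ± 1.33 CPM (−4.98, SE 0.23, edgeR adjusted p = 7.07e-09; −4.80 in dKO, 8.7e-09). G0s2, an inhibitor of fat breakdown (−4.36 in WT, −4.28 in dKO), Atp1b4 (−4.35, −4.13), the neurotrophin Ntf5 (−4.31, −4.71), Asb18 (−4.04, −4.20), Kbtbd13 (−4.03, −4.31) and Sec14l5 (−3.96, −3.90) fell in both genotypes. Exons of Gdf5, Krt8, Fosl1, Rrad, Syt4, Cxcl10 and, among genes described below, Gadd45a, Runx1, Hdac4 and Fbxo32 overlap a gene on the other strand and are uncertain in that respect.

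The list of genes of the neuromuscular synapse and of the known denervation programme had the highest median. Of 26, 15 rose and 6 fell in WT (median 2.11, camera adjusted p = 5.29e-05, with an estimated correlation 0.28) and 16 rose and 5 fell in dKO (median 2.07, camera adjusted p = 1.2e-05, with an estimated correlation 0.264). The myogenic factor Myog went from 6.86 to 285 CPM in WT (5.38, SE 0.19, edgeR adjusted p = 9.09e-10) and from 5.43 to 326 CPM in dKO (5.91, edgeR adjusted p = 4.95e-10). Gadd45a, which takes part in the remodelling of nuclei in denervated fibres, rose by 5.08 in each genotype, in WT from 13.1 to 443 CPM, and the transcription factor Runx1 by 4.61 and 4.66. The receptor subunit Chrnd rose by 4.21 and 4.42 (in WT from 1.94 to 36.1 CPM), Chrna1 by 3.34 and 3.47 (12.2 to 124 CPM), and the synaptic kinase Musk by 3.79 and 3.83 (13.8 to 192 CPM). Hdac4, a repressor that links loss of the nerve to these genes, rose by 2.93 and 2.95 (49.5 to 377 CPM), and Myod1 by 2.30 in dKO and from 15.8 to 71.4 CPM in WT. Those that fell included Ache (−2.43 and −1.97), which splits acetylcholine at the synapse, Hdac9 (−2.10 and −1.67) and the adult receptor subunit Chrne (−0.79 and −0.71), named here after their values were seen. Dach2 fell in WT (−1.46, edgeR adjusted p = 8.42e-05) and in dKO (−1.21, 0.000948). The embryonic subunit Chrng was called at 2.76 (SE 0.94, edgeR adjusted p = 0.0286) and 2.88 (SE 0.97, 0.0297). Its call ended without WT_innervated 1 (adjusted p = 0.0942 by edgeR), WT_innervated 2 (0.0869) or WT_denervated 3 (0.0878), and in dKO without dKO_innervated 1 (0.0933), dKO_innervated 2 (0.102) or dKO_denervated 3 (0.143). Ncam1 was at 0.28 in WT (adjusted p = 0.339 by edgeR) and 0.44 in dKO (0.13; 0.037 with a term for replicate number, range over alternatives 0.0206 to 0.536).

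**Figure D3:**
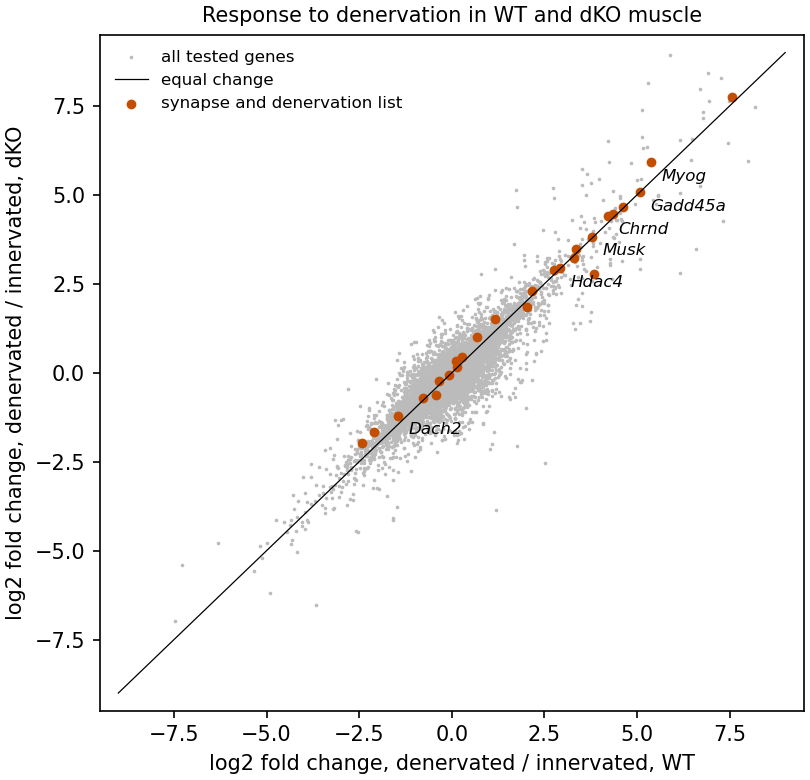
Log2 change after denervation in WT (x) and dKO (y) for all 17201 tested genes (grey), with 26 synaptic and denervation-responsive genes in orange and the line of equal change. The 26 lie near the line (Pearson 0.993), with a largest difference between genotypes of 1.07 in size. Those labelled run from Myog at 5.38 and 5.91 down to Dach2 at −1.46 and −1.21.

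The machinery of protein breakdown rose. The muscle ubiquitin ligase Fbxo32 (atrogin-1) went from 91.3 to 1046 CPM in WT (3.52, SE 0.33, edgeR adjusted p = 2.8e-06; 3.26 in dKO, 4.71e-06) and Trim63 (MuRF1) from 113 to 1003 CPM (3.15, SE 0.25, edgeR adjusted p = 7.04e-07; 3.27 in dKO). On their list 11 rose and 6 fell of 18 in WT (median 0.46, camera adjusted p = 0.0676, with an estimated correlation 0.294), and 11 rose and 4 fell in dKO (0.54, camera adjusted p = 0.0368, with an estimated correlation 0.274). All 31 proteasome genes rose in each genotype, median 0.86 (camera adjusted p = 1.8e-12 in WT and 3.67e-14 in dKO, with an estimated correlation 0.302 and 0.347), led by Psma5 (1.42 and 1.42; it has a near-identical copy), Psmd8 (1.23, 1.31) and Psmd14 (1.16, 1.22). Of 23 autophagy and lysosome genes 15 rose and 2 fell in WT (median 0.32, camera adjusted p = 0.000926, with an estimated correlation 0.308) and 13 rose and 1 fell in dKO (0.31, 0.000204 and 0.347). Gabarapl1 (2.31 and 2.43), the cathepsin gene Ctsl (2.15 and 2.08) and the autophagy receptor Sqstm1 (2.00 and 1.98) led them.

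Energy metabolism fell. Of 48 nuclear genes of oxidative phosphorylation 43 fell and 0 rose in WT (median −0.45, camera adjusted p = 1.16e-11, with an estimated correlation 0.302), and 37 fell and 0 rose in dKO (−0.43, 1.13e-10 and 0.347), or 46 and 42 adjusted over the list alone. Ndufb10 (−1.04 and −0.91) and Sdhd (−1.01 and −1.03) were the leading members. The citrate cycle and fat oxidation list had 23 of 34 fall in WT and 24 in dKO, 0 rise (medians −0.33 and −0.33; camera adjusted p = 4.6e-07 and 1.11e-06, with an estimated correlation 0.302 and 0.347). The nuclear receptors Ppara (−2.04, −2.17) and Esrra (−1.84, −1.66), which drive this programme, fell. The list was led by the coactivator Ppargc1a, which fell from 50.1 to 10.9 CPM in WT (−2.20, SE 0.12, edgeR adjusted p = 2.63e-08) and in dKO too (−2.53, 8.9e-09). Of 22 genes of glycolysis and glycogen 17 fell in WT (median −0.62, camera adjusted p = 6.88e-08, with an estimated correlation 0.294) and 16 in dKO (−0.71, 3.6e-07 and 0.347) and 0 rose, led by glycogen synthase Gys1 (−1.93, −1.73). Mitochondrially encoded genes fell in 6 of 12 in WT (median −0.41, camera adjusted p = 0.0126, with an estimated correlation 0.556) and 5 in dKO (−0.41, 0.021 and 0.573).

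Contractile and excitation genes fell too, though the main myosin of fast fibres did not pass. Myh4 was at −0.33 in WT (edgeR adjusted p = 0.154; 0.0381 without WT_innervated 2) and −0.15 in dKO (0.553). Pvalb, the calcium buffer of fast fibres, was at −0.29 in WT (edgeR adjusted p = 0.0681; 0.0459 with a term for replicate number, range over alternatives 0.0188 to 0.751). In dKO it was called at −0.33 (adjusted p = 0.0428 by edgeR), and lost that call without dKO_innervated 1, 2 or 3 (0.0523, 0.0806 and 0.134) and without dKO_denervated 1, 2 or 3 (0.0628, 0.127 and 0.125). The difference between the genotypes in this response was −0.04 (edgeR adjusted p = 1). Fast-fibre genes fell in 12 of 16 in WT (median −0.44, camera adjusted p = 3.71e-05, with an estimated correlation 0.302) and 10 in dKO (−0.42, 0.000204 and 0.347), led by the enolase Eno3 (−1.40, −1.34) and calsequestrin Casq1 (−0.96, −1.11). Slow-fibre genes fell in 6 and rose in 1 of 13 in WT (median −0.81, camera adjusted p = 0.0626, with an estimated correlation 0.294; with a term for replicate number 0.0288, and 0.365 with an estimated correlation) and fell in 5 and rose in 1 in dKO (−0.76, 0.0386 and 0.306). Myh2 (−2.32, −2.34), which encodes the myosin of oxidative fast (IIa) fibres rather than slow ones, and Casq2 (−2.19, −1.96) had the largest changes on this list. Core sarcomere genes fell in 14 of 23 in WT (median −0.62, camera adjusted p = 9.73e-06, with an estimated correlation 0.294), led by Lmod3 (−3.05), a leiomodin of thin filaments, and Csrp3 (−2.29). In dKO 13 fell and 2 rose (−0.48, camera adjusted p = 0.000706, with an estimated correlation 0.347), with Lmod3 at −3.17 and Mybph rising by 1.95. Calcium and excitation genes fell in 17 and rose in 1 of 23 in WT (median −0.54, camera adjusted p = 9.73e-06, with an estimated correlation 0.294) and fell in 13 and rose in 2 in dKO (−0.56, 0.00035 and 0.347). Kcnc1, given above, led them, before the potassium channel Kcna7 (−3.46, −3.19) and the sodium pump subunit Atp1b1 (−2.84, −2.64).

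Stress programmes rose. Of 24 immediate early genes 11 rose and 2 fell in each genotype (medians 0.71 and 0.86; camera adjusted p = 0.0213 and 0.00105, with an estimated correlation 0.507 and 0.347), with Fosl1 first and Atf3 (3.47, 3.62) second. On the p53 list 12 rose and 2 fell of 22 in WT (median 0.70, camera adjusted p = 0.0107, with an estimated correlation 0.28) and 10 rose and 2 fell in dKO (0.46, 0.0203 and 0.264). The receptor Eda2r led (4.56, 4.31), and the cell-cycle inhibitor Cdkn1a rose as well (3.83, 2.77). Unfolded-protein and integrated-stress genes rose in 17 and fell in 1 of 21 in each genotype (medians 0.91 and 1.06; camera adjusted p = 2.32e-06 and 1.76e-06, with an estimated correlation 0.28 and 0.264). The hormone Fgf21 led (5.12, 6.63), and the one that fell was Ddit3 (−1.88, −1.52), which encodes CHOP. Heat-shock genes rose in 12 and fell in 2 of 18 in WT (median 0.47, camera adjusted p = 0.00528, with an estimated correlation 0.498) and rose in 9 and fell in 2 in dKO (0.65, 0.00196 and 0.452), led by Hspb8 (2.77, 3.07). The polyamine enzyme Odc1 rose (3.33, 3.12) and Smox fell (−2.19, −2.24). Their list had 4 rise and 2 fall of 12 in each genotype (median 0.09, camera adjusted p = 0.518, with an estimated correlation 0.784 in WT; median −0.01 with a mean of 0.12 in dKO, 0.565 and 0.763).

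Ribosome and H2A.Z-handling genes rose by less. Ribosomal proteins rose in 31 of 40 in WT and 36 in dKO (medians 0.42; camera adjusted p = 6.88e-08 and 9.86e-09, with an estimated correlation 0.354 and 0.347), led by Rpl3 (1.89, 1.96; it has 3 near-identical copies). Genes that deposit or remove H2A.Z rose in 13 and fell in 1 of 23 in WT (median 0.34, camera adjusted p = 0.00428, with an estimated correlation 0.28) and rose in 12 with 0 falling in dKO (0.27, 0.00166 and 0.264). The remodeller Ino80 led in WT (0.74, 0.68 in dKO) and Vps72, an H2A.Z-binding subunit, in dKO (0.71). Proliferation genes rose in 14 and fell in 3 of 28 in WT (median 0.66, camera adjusted p = 0.00851, with an estimated correlation 0.354), led by the mitotic kinase Aurkb (1.78) and Cenpe (1.45). In dKO 8 rose and 3 fell (0.43, camera adjusted p = 0.161, with an estimated correlation 0.635), led by Aurka (−1.11) and Rrm2 (1.00). Of the clock genes 5 rose and 2 fell of 19 in WT and 5 rose and 1 fell in dKO (medians −0.07 with means of 0.04 and 0.10; camera adjusted p = 0.774 and 0.628, with an estimated correlation 0.878 and 0.763). The first was Bhlhe41 (−2.20, −1.95). The clock activator Arntl was called at 1.36 (SE 0.40, edgeR adjusted p = 0.0147) and 1.34 (0.0168). That call ended without WT_innervated 1 (adjusted p = 0.0626 by edgeR), WT_innervated 3 (0.0593) or WT_denervated 2 (0.0584), and in dKO without dKO_innervated 2 (0.0691), dKO_innervated 3 (0.0708) or dKO_denervated 1 (0.065).

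Genes of other cell types moved in different directions. Schwann-cell genes split, 5 rising and 8 falling of 15 in each genotype (medians −0.89 and −1.003; camera adjusted p = 0.212 and 0.117, with an estimated correlation 0.605 and 0.57). Cldn19, a claudin of myelin, fell (−3.23, −3.19) and Ngfr, a marker of injured Schwann cells, rose (2.97, 2.99). Matrix-producing fibroblast genes fell in 13 and rose in 1 of 20 in WT (median −0.80, camera adjusted p = 0.000926, with an estimated correlation 0.318), led by Col5a1 (−1.29) and Clec3b (−1.23). In dKO 12 fell and 1 rose (−0.56, camera adjusted p = 0.00805, with an estimated correlation 0.441), led by Col1a1 (−1.18), whose call ended without dKO_innervated 3 (0.0856). Mural-cell genes fell in 9 of 12 in WT and 8 in dKO (medians −0.64 and −0.63; camera adjusted p = 0.00044 and 0.000829, with an estimated correlation 0.28 and 0.28), led by Cnn1 (−1.18, −1.18). Endothelial genes fell in 10 of 15 and in 6 (medians −0.39 and −0.25; camera adjusted p = 0.00543 and 0.0283, with an estimated correlation 0.302 and 0.352), led by the VEGF receptor Kdr (−1.05, −1.03). Macrophage and myeloid genes rose in 6 and fell in 1 of 20 in WT (median 0.38, camera adjusted p = 0.0626, with an estimated correlation 0.565; with a term for replicate number 0.0437, and 0.365 with an estimated correlation) and rose in 3 and fell in 1 in dKO (0.09, 0.216 and 0.704), led by S100a8 and Cd68 (2.01, 2.31). Interferon-induced genes fell in 1 of 24 in WT (median −0.19, camera adjusted p = 0.358, with an estimated correlation 0.861), and in 4 in dKO (median −0.29, 0.0452 and 0.704). Erythroid genes had 1 of 8 fall in each genotype, Bpgm (−0.99, −1.03; medians −0.28 and −0.54, camera adjusted p = 0.134 and 0.0452, with an estimated correlation 0.644 and 0.57; in WT with a term for replicate number 0.0486, and 0.404 with an estimated correlation). The nuclear noncoding RNAs fell in 4 of 6 in each genotype (median −1.06, camera adjusted p = 0.0468, with an estimated correlation 0.498 and 0.0595 with a term for replicate number in WT; −0.61, 0.345 and 0.724 in dKO). Miat (−1.29) and Mirg (−1.21) led in WT and Meg3 (−0.69) in dKO.

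Some members moved against their list, and those named here were picked after their values were seen, most of them without a run for each left-out library. Among immediate early genes the orphan nuclear receptor Nr4a1 fell (−2.29 in WT, −2.34 in dKO), as did the phosphatase Dusp1 (−0.95, −0.93), which switches off MAP kinases. On the p53 list the fall was in the DNA polymerase Polk (−0.97, −1.02) and the cyclin Ccng1 (−0.62, −0.67), and among heat-shock genes in the small chaperones Hspb6 (−1.61, −1.44) and Hspb2 (−0.76, −0.64). Trim55 (MuRF2), a relative of Trim63, fell (−1.13, −1.16), with Fbxo21 (−0.32, −0.40), Cblb (−0.47, −0.52) and Nedd4 (−0.27, −0.31) in both genotypes. Among autophagy genes the kinase Ulk2 fell in both (−0.32, −0.37) and the lysosomal regulator Tfeb in WT (−0.60). The slow calcium pump Atp2a2 (0.42, 0.42) and the calcium channel subunit Cacng1 (0.86, 1.04) rose on lists in which most called genes fell, as did Sln on the latter list in dKO (1.28). Znhit1 was the member of the H2A.Z deposition list that fell in WT (−0.50), and the scavenger receptor Cd163 the macrophage gene that fell (−0.74, −0.37). Of the proliferation genes Aurka (−0.92, −1.11), Mcm2 (−0.56, −0.71) and Tk1 (−0.65, −0.95) fell in both genotypes.

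Adjusted over the list alone, some counts after denervation differ from those above. In WT the genes that fell were then 26 for the citrate cycle and fat oxidation, 14 for fast fibres, 16 for the core sarcomere (1 rose), 7 for mitochondrially encoded genes, 14 for matrix-producing fibroblasts, 10 for mural cells, 3 for immediate early genes and 2 for H2A.Z deposition. Those that rose were 18 for unfolded-protein and integrated-stress genes, 33 for ribosomal proteins and 16 for proliferation. In dKO the genes that fell were 18 for glycolysis, 13 for fast fibres, 6 for slow fibres, 5 for ubiquitin ligases, 2 for unfolded-protein and integrated-stress genes and 1 for interferon-induced genes. Those that rose in dKO were 17 for the synaptic list, 14 for autophagy, 13 for H2A.Z deposition and 1 for the citrate cycle and fat oxidation, and macrophage genes had 2 rise and 0 fall.

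The share of genes that rose depends on scaling. Scaled by library totals alone the median of all genes was 0.236 in WT and 0.148 in dKO, against −0.003 and −0.026 with TMM, and the part of called genes that rose went from 52.4% to 76.5% and from 52.0% to 71.6%. The called lists kept their sign, but the oxidative phosphorylation genes called as falling in WT went from 43 to 17, the citrate cycle from 23 to 12, the fast-fibre genes from 12 to 6, the mitochondrially encoded from 6 to 0 and the endothelial from 10 to 3, with 1 rising. In dKO they went from 37 to 25, 24 to 13, 10 to 7, 5 to 1 and 6 to 3, with 2 endothelial genes rising. Macrophage genes called as rising went from 6 to 13 in WT and from 3 to 4 in dKO. Among lists not called, medians that turned positive included those of the clock genes (0.18 and 0.10), of the interferon-induced genes in WT (0.05) and of the polyamine genes in dKO (0.17).

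**Figure D4:**
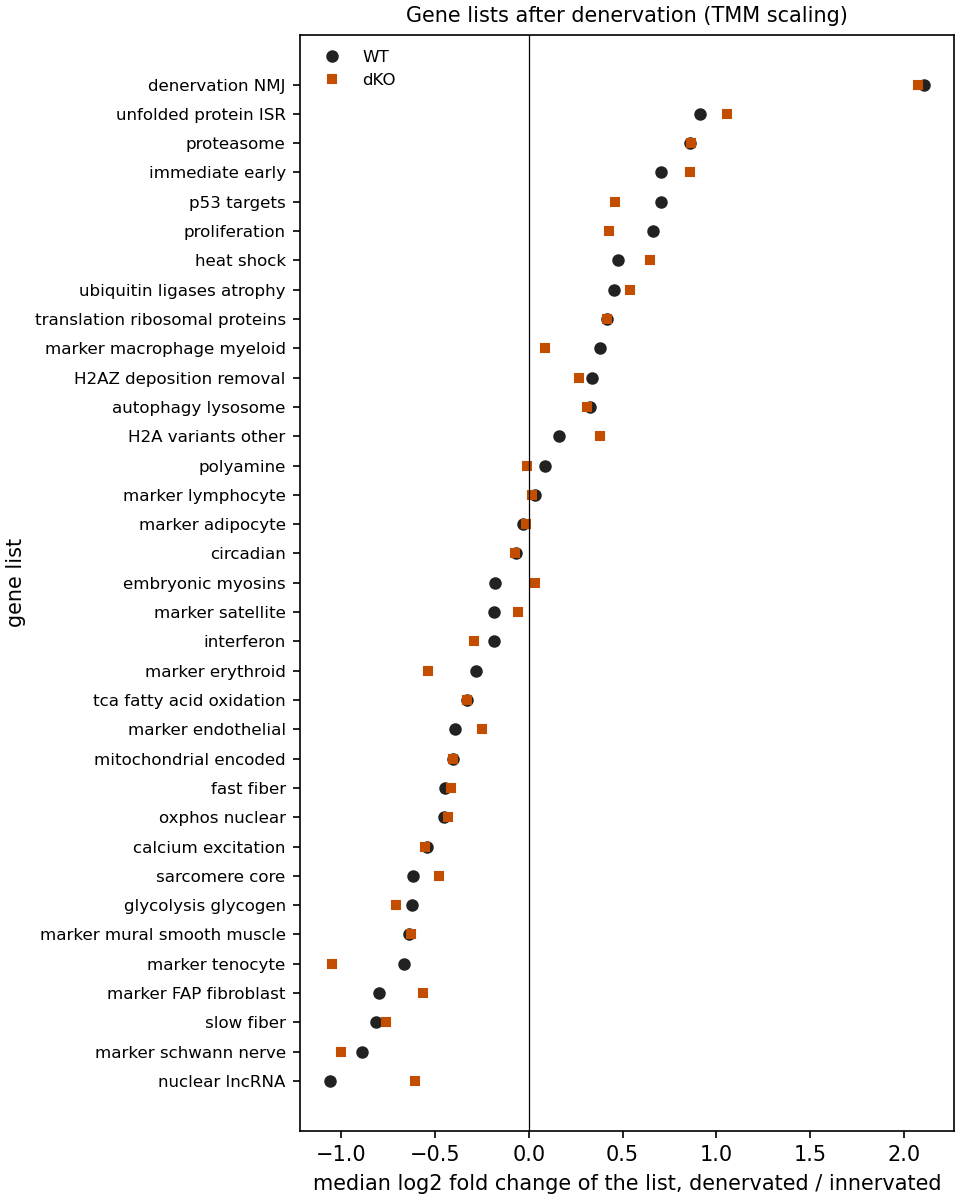
Median log2 change after denervation of 35 gene lists in WT (dots) and dKO (squares), TMM scaling. Synaptic and denervation-responsive genes stand highest (2.11 and 2.07), and oxidative phosphorylation is below 0 in both (−0.45 and −0.43).

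Whether the response to denervation differs between genotypes was tested gene by gene as an interaction, and 0 genes passed with edgeR's quasi-likelihood test, DESeq2 or limma-voom. Unadjusted p below 0.05 was reached by 374 genes with edgeR and 360 with limma-voom, fewer than the 860 expected by chance, and by 401 with DESeq2, which was run on all 31057 genes. These fits take the legs as independent though legs of equal number vary together, so the low counts do not show equal responses. With edgeR the count was 316 without dKO_denervated 2 and 772 without WT_denervated 1. With a term for replicate number 0 passed and 668 had an unadjusted p below 0.05, and 2 passed, both negative, without a filter on low counts. Among the single genes chosen in advance for this contrast, the largest difference was in Myog, 0.54 (SE 0.23, edgeR adjusted p = 1). Ppargc1a differed by −0.33 (SE 0.16), Fbxo32 by −0.26 (SE 0.42), Dach2 by 0.25, Chrnd by 0.20, Trim63 by 0.12, Chrna1 by 0.12, Runx1 by 0.05, Musk by 0.03, Hdac4 by 0.02 and Gadd45a by 0.01, each with adjusted p = 1 by edgeR. In the fit without a term for replicate number, the 95% interval lay within a 2-fold difference for 71.7% of tested genes, and for 92.1% of those with a mean of at least 1 CPM. It lay within a 1.5-fold difference for 49.8% and 67.4%. The 2 responses ran together over all genes (Pearson 0.905, Spearman 0.855). Of genes called in WT, 7511 (99.1%) had the same sign in dKO, and 3340 were called up and 2909 down in both, against 867.6 and 728.27 by chance, with 0 opposite. All 26 synaptic and denervation-responsive genes had the same sign in both, and their list differed by a median of 0.12 (camera adjusted p = 0.114 at the preset correlation, 0.984 with an estimated correlation). The largest difference among these 26 was 1.07 in size. Of them 2 had an unadjusted p below 0.05 by edgeR, the smallest 0.015.

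In their response 5 lists differed by camera at its preset correlation, with 0 member genes called in any of them and adjusted p = 0.984 for each with an estimated correlation. Proliferation genes responded less in dKO (median difference −0.27, camera adjusted p = 0.000372), a list that rose in WT. Both legs enter this difference: the median of dKO over WT was 0.20 in innervated and −0.20 in denervated legs. Nuclear noncoding RNAs (0.42, camera adjusted p = 0.0016) and core sarcomere genes (0.13, 0.00147) fell by less in dKO. Calcium and excitation genes (0.16, camera adjusted p = 0.00999) and immediate early genes (0.20, 0.00703) had positive differences. For immediate early genes the median of dKO over WT was −0.14 in innervated and 0.10 in denervated legs. With a term for replicate number 8 lists passed, adding the proteasome (camera adjusted p = 0.0394, 0.136 without it), interferon-induced genes (0.0325, 0.0646) and matrix-producing fibroblast genes (0.0325, 0.0646), each with an adjusted p = 0.928 in that fit with an estimated correlation. Leaving out libraries ended calls by camera. Core sarcomere was lost without WT_denervated 3 (adjusted p = 0.102), proliferation without WT_innervated 1 (0.1) and the noncoding RNAs without dKO_innervated 2 (0.0648). Immediate early was lost without WT_denervated 2 (adjusted p = 0.551 by camera), WT_innervated 3 (0.162) or dKO_innervated 1 (0.129). Calcium and excitation was lost without WT_innervated 3 (adjusted p = 0.162 by camera), WT_denervated 3 (0.102), dKO_innervated 1 (0.138), dKO_denervated 1 (0.143) or dKO_denervated 2 (0.0838).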

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

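The tests of GC content on the genes called between genotypes were chosen only after those calls were seen, and so were the GC correction, the GC correction together with the replicate block, and the fit without the 2 low-GC libraries. For 5 gene lists the response to denervation differed between dKO and WT in camera's test of the difference at the preset correlation, which brings them here: core sarcomere genes (adjusted p = 0.00147), calcium and excitation genes (0.00999), immediate early genes (0.00703), proliferation genes (0.000372) and nuclear noncoding RNAs (0.0016).

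The first pattern is these 5 lists. With the replicate block and each library's GC trend removed, 4 of the 5 stayed called by camera. Calcium and excitation genes missed the threshold there, at a median of 0.12 against 0.16 before (camera adjusted p = 0.0501). The block alone kept all 5 and gave 8 called lists, and the GC correction was not run on lists without it. These calls therefore do not separate the 2 changes. Core sarcomere genes had a median of 0.14 against 0.13 before, and immediate early genes 0.21 against 0.20. Proliferation genes had −0.25 against −0.27, and noncoding RNAs 0.46 against 0.42. These medians, little changed, argue against GC content bias as the whole cause. One library as the cause stays open, since leaving out dKO_innervated 1, WT_denervated 3 or WT_innervated 3 ended 2 of the 5 calls each. With an estimated correlation all 5 miss the threshold (adjusted p = 0.984 for camera), and 0 member genes pass alone by edgeR. An effect of the genotype on the response is a hypothesis that stays untested beyond these values.

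The second pattern is the set of genes called between genotypes, 79 in innervated and 62 in denervated legs. With each library's GC trend removed 72 of the 79 and 62 of the 62 stayed called in the same direction. Median sizes were 0.812 before and 0.785 after in innervated and 0.76 and 0.743 in denervated legs. This argues against GC content bias as the whole cause. Over all tested genes the change correlated with GC content (Spearman) at −0.296 before and −0.012 after in innervated legs, and at −0.041 and 0.024 in denervated legs. Without the 2 low-GC libraries 42 of the 79 and 32 of the 62 stayed called, on fewer libraries. A chromosome segment of another strain predicts called genes next to each other. Of 104 called genes, 8 had another called gene among the 10 nearest tested genes on either side. Random sets matched on expression gave a median of 12 and a 95th percentile of 20 (permutation p = 0.88). This count over all chromosomes cannot decide on a single segment that holds few called genes. Among the 8 were Gins1 and Snph, both on chromosome 2. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many calls in each leg, with the highest other at 0 in innervated and 1 in denervated legs. Loss of H2A.Z, a small chromosome segment of another strain, other differences between the animals including Cre itself, and differences in cell content stay open.

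The third pattern is that H2afz kept 62.2% and 67.6% of its control level in dKO where H2afv kept 25.6% and 24.1%. Reads shared with near-identical copies are a candidate explanation: H2afz has 1 such copy among annotated transcripts, within Tmcc1, and H2afv has 0. Counts are listed at Tmcc1, but they come from its own sequence as well, so the amount shared is not known from them. Cells in which HSA-Cre is not active, such as blood vessel and connective tissue cells, may also hold unchanged H2afz, and this was not tested. Incomplete recombination in muscle fibres was not tested either. The counts are per gene, so they do not show which part of H2afz the remaining reads cover or whether its transcript is intact.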

How the results depend on the processing

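Chosen only after the results were seen were the GC correction, the GC correction with the replicate block, the fit without WT_denervated 2 and dKO_innervated 1, and the test of summed legs. The denervation counts stayed within 1.5 times under each alternative except a 2-fold limit, which left 2030 genes in WT and 1965 in dKO. Left-out libraries gave 6479 to 7082 genes in WT and 6115 to 6681 in dKO, of which 6312 to 6628 and 5948 to 6273 were among those called with all libraries. The genotype counts depend on the method. In innervated legs (79) they were 264 with DESeq2 and its own filter, 240 without a filter, 50 without the 2 low-GC libraries, 46 with only the groups compared and 29 with a 2-fold limit. In denervated legs (62) they were 289 with DESeq2 and its own filter, 252 without a filter, 102 with the GC correction, 127 with the GC correction and replicate block, 4 with only the groups compared and 20 with a 2-fold limit. Left-out libraries gave 27 (without dKO_innervated 2) to 52 (without dKO_innervated 3) in innervated and 11 (without dKO_denervated 2) to 42 (without WT_denervated 2) in denervated legs. The number in the fit with only the groups compared rests on fewer libraries for the spread, and for the others the cause was not tested. The fit of all 12 libraries takes the legs as independent, though legs of equal number vary together. Its 8 residual degrees of freedom may therefore overstate what is known of the spread between animals, and its genotype counts may be too high. Which of the 2 fits is nearer was not tested. For the genotype contrasts equal numbers did not mark closer libraries (correlations of −0.234 to 0.414 in innervated and −0.423 to 0.236 in denervated legs). Correlations across genotypes were highest between WT 1 and dKO 2, at 0.494 in innervated and 0.583 in denervated legs. Legs of equal number vary together, so these values are not independent, and their cause was not tested. The replicate block gave 82 and 87 genes. Macrophage genes in denervated legs passed by camera with it (adjusted p = 0.0359, and 0.798 with an estimated correlation). Of the 19 named genes in innervated legs, 11, 9 and 11 stayed called without WT_innervated 1, 2 and 3 and 14, 10 and 13 without dKO_innervated 1, 2 and 3. Of the 18 in denervated legs it was 9, 11 and 4 without WT_denervated 1, 2 and 3 and 7, 4 and 8 without dKO_denervated 1, 2 and 3. The replicate block ended or added no call of a named gene or list after denervation or in the interaction other than those given in the report, apart from Ccr2 in WT (0.70), which ended (adjusted p = 0.0596). The interaction count of 0 became 2 without a filter (unadjusted 831).

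H2afz in innervated legs passed with DESeq2 (−0.69, adjusted p = 0.0359), without a filter (−0.69, 0.00528), with the replicate block (−0.68, 0.0397) and with block and GC correction (−0.70, 0.0405), and in denervated legs without a filter (−0.57, 0.0434). The block adds the replicate number to a contrast between animals, whose numbers did not mark closer libraries across genotypes, and with the legs of each number summed H2afz did not pass (−0.62, adjusted p = 0.204). After denervation in WT it passed with DESeq2 (−0.48, adjusted p = 0.0416), limma-voom (−0.50, 0.0375), no filter (−0.47, 0.0103), the filter at 1 CPM (−0.48, 0.0448), the GC correction (−0.50, 0.0463), the replicate block (−0.48, 0.00656) and both (−0.51, 0.0061), and left-out libraries gave −0.60 to −0.31. In dKO it passed with the replicate block (−0.35, adjusted p = 0.035) and with both (−0.35, 0.0425). The cause was not tested. H2afv was called between genotypes under 20 of 20 alternatives in each leg. Its denervation value in WT turned to 0.14 with library totals only (adjusted p = 0.404), as did Myh4 in dKO (0.026, adjusted p = 0.905).

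Interaction values of the named genes are imprecise, and over the alternatives 57 of 474 changed sign, none past the threshold (smallest adjusted p = 0.998 by edgeR, DESeq2 or limma-voom). With library totals only these were Musk −0.032, Runx1 −0.012, Gadd45a −0.063 and Hdac4 −0.044. Without the low-GC libraries they were H2afz −0.023, Chrng −0.51, Myod1 −0.14, Gadd45a −0.22, Fbxo32 0.33 and Arntl 0.75. Chrng was −1.38 with limma-voom, −0.35 with the replicate block and −0.30 with block and GC correction, and Arntl 0.006 with DESeq2 and 0.027 with the GC correction. Left-out libraries gave ranges of −0.025 to 0.258 for H2afz, −0.161 to 0.03 for H2afv, −0.097 to 0.248 for Chrna1, −3.407 to 1.367 for Chrng, −0.103 to 0.189 for Musk, −0.22 to 0.535 for Myod1, −0.059 to 0.175 for Runx1, −0.105 to 0.355 for Ncam1, −0.154 to 0.167 for Gadd45a, −0.571 to 0.173 for Fbxo32, −0.158 to 0.385 for Trim63, −0.021 to 0.111 for Hdac4, −0.116 to 0.434 for Dach2, −0.04 to 0.351 for Myh4, −0.164 to 0.05 for Pvalb and −0.554 to 0.498 for Arntl. The 3 genes that kept their sign throughout were Myog (0.396 to 0.766 with left-out libraries), Ppargc1a (−0.44 to −0.241) and Chrnd (0.099 to 0.327). The lists called fell to 0 in each of the 5 comparisons with an estimated correlation, and the interaction had 8 with the replicate block. The agreement of the denervation effects was 0.963 (Pearson) and 0.94 (Spearman) at 1 CPM in at least 3 libraries, and 0.865 to 0.893 and 0.803 to 0.849 with left-out libraries. The genotype intervals within 1.5-fold made up 60.1% and 61.7% of genes, and those within 2-fold 74.7% to 76.1% and 76.1% to 77.6% with left-out libraries, against 80.3% and 82.2%.

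Chance was tested with other splits of the libraries. For the denervation counts 1 of 10 splits, the real one, gave as many calls in each genotype (7576 in WT and 7233 in dKO, highest other 0 and 0), and 10 splits are too few for a share under 0.05. For the interaction the real count is 0, so that all 100 splits give as many, and this count says nothing about chance. The highest of the others called 552 genes and the next 4. That split exchanges the genotype labels in innervated legs only. It thus sums the genotype effects of both legs, takes the legs as independent samples and is not a split by chance. With the 2 legs of each replicate number summed, the genotype effect gave 48 genes by edgeR, with fewer samples to measure the spread. How much of the 552 comes from taking the legs as independent was not tested. On simulated data the procedure called 36.4% of genes with a 1.5-fold, 65.2% with a 2-fold and 90.8% with a 4-fold change between genotypes in innervated legs, and 10.6%, 36.9% and 73.4% in the interaction. The simulated counts were independent between libraries, with no GC trend and no link between legs of equal number. The shares may therefore differ in the real data. The interaction interval lay within 2-fold for 92.1% of genes at 1 CPM or more against 71.7% of all, and the part of depth in this was not tested.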

Other observations

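The authors' deposited table can be set beside the counts given here. At their adjusted p-value below 0.05 it lists 266 genes between genotypes in innervated legs (110 higher and 156 lower in dKO) and 292 in denervated legs (133 and 159), and 7566 and 7256 genes after denervation in WT and dKO. Genes shared with those called here number 79, 59, 7362 and 7030, all with the same sign, and the log2 fold changes correlate at 0.951, 0.965, 0.973 and 0.968 over the genes tested.

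Some of the gene groups not described above are given here, after denervation. Lymphocyte markers had 0 of 8 called in each genotype (camera adjusted p = 0.819 and 0.974, with an estimated correlation 0.903 and 0.983). Adipocyte markers had 1 of 14 fall in each (medians −0.03 and −0.02; camera adjusted p = 0.524 and 0.656, with an estimated correlation 0.86 and 0.87), with medians of 0.22 and 0.17 when scaled by library totals only. Among histone genes other than H2A.Z, 1 of the 10 H2A and H3 variants on the list rose in each genotype, H3f3b (0.88 in WT and 1.17 in dKO; camera adjusted p = 0.819 and 0.432, with an estimated correlation 0.909 and 0.763). Tendon markers had 1 rise and 3 fall of 10 in WT (6 fall adjusted over the list alone) and 1 rise and 7 fall in dKO (medians −0.66 and −1.05; camera adjusted p = 0.212 and 0.0816, with an estimated correlation 0.728 and 0.621). Satellite-cell markers had 3 rise and 4 fall of 13 in WT and 2 rise and 3 fall in dKO (medians −0.18 and −0.06 with means of 0.08 and 0.14; camera adjusted p = 0.774 and 0.924, with an estimated correlation 0.878 and 0.966). Scx, a transcription factor of tendon cells, was the tendon marker that rose (1.94 and 2.55).

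The test of summed legs was chosen only after the genotype results were seen. With the 2 legs of each replicate number added, 3 dKO against 3 WT sums gave 48 genes called by edgeR (14 higher and 34 lower in dKO) of 18115 tested, with 1882 at an unadjusted p below 0.05. Of the 48, 41 were also called in a leg alone. H2afv was at −2.01 (adjusted p = 0.000237 by edgeR) and H2afz at −0.62 (0.204) in these sums.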
